A study of Mus musculus with 2 samples.

How the data were processed

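RNA of a conditionally immortalized mouse podocyte line was measured on Affymetrix murine genome arrays, 1 array for undifferentiated cells and 1 for differentiated cells. The line carries the Immorto transgene, which keeps cells dividing at 33 °C in the presence of interferon gamma. Per the labels' protocols, the undifferentiated cells were grown at 33 °C with interferon gamma on collagen I, and the permissive medium held 10% serum and 100 U/ml interferon gamma. The differentiated cells were moved to 37 °C without interferon gamma, in 5% serum, for at least 10 days, and were described as growth arrested. Groups were taken from the sample titles. Per the labels, RNA was isolated with an Ambion kit from the differentiated cells and with a Qiagen kit from the undifferentiated cells, so RNA kit and group cannot be told apart.

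The authors deposited intensity values in 2 tables. The value table holds 1 signal on a linear scale for each of 45037 probe sets, plus 64 control probe sets, on both arrays. It gives no gene names. The GAP and GEF table holds 374 of these probe sets with gene names, and for each group a signal, a present, marginal or absent call and a standard error. GAPs switch small GTPases off and GEFs switch them on. Analysis with dChip is named in the labels' protocol of the differentiated sample. The baseline, the model options, the version and the normalization between arrays are not given in the sources used here. The standard error is read as dChip's model error over the probes of 1 array, a technical error that holds no variation between cultures.

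The columns were assigned to groups by their names, and the values were then compared. The undifferentiated column of the GAP and GEF table equalled that of the value table within 0.005 signal units for all 374 probe sets. The differentiated column equalled the value table's for 0 of 374. The origin of this second differentiated column is not given in the sources used here, so both were analysed and are named separately throughout. Whether it comes from the same cells, the same RNA or another scan stays unknown.

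The GAP and GEF table was used as deposited, with no further scaling. A gene was measured where its probe set was called present in at least 1 group. Of the 374 probe sets, 366 belong to 1 gene ID and 8 to several, and the 8 were left out. The 366 covered 168 genes. Gene IDs were matched to a table of RefSeq genes of the assembly GRCm38.p6, used for names alone: 167 IDs matched, 1 did not, and 15 symbols were updated. Each gene was represented by the probe set with the highest mean log2 signal over both groups. The error of a log2 difference was propagated from the deposited standard errors of both signals. Where a probe set was absent in 1 group, its level there was set to a reference. This was the higher of its own signal and the lowest present signal of that group. The difference is called a bound, though absent-called signals can lie above that reference.

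The value table's intensity values were raised to at least 1, and log2 was taken. The interquartile ranges of the 2 arrays' log2 signals were 4.79 (undifferentiated) and 3.92 (differentiated). They differed by 22.3%, over the 10% set before the data were examined as the limit for median centring, so quantile normalization between the 2 arrays was used. Normalized values under the 40th percentile of the pooled normalized data, 37.6 signal units, were set to it. A probe set was measured where at least 1 array lay above it. Signals of the value table are printed as deposited, before normalization, so a printed signal near 37.6 can lie on the other side of the floor. Counts for the whole array are of probe sets, because names were used here for the probe sets of the GAP and GEF table alone. This departs from the plan of 1 probe set per gene.

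With 1 array per group no test across samples was possible and no p-value is given. The number of arrays limits the precision. Changes are named by size, with at least 2-fold as the threshold. Of 24 gene lists fixed before the data were examined (among them podocyte markers, cell cycle, interferon response, heat shock, matrix, markers of other kidney cells and leukocytes), 19 had no member among the named probe sets, 2 had 1 member, and the results of the other 3 are not reported here. The median of a list was set beside the medians of 10000 random lists of the same size, matched on mean level in 20 bins. In the GAP and GEF table these lists were drawn from its measured genes, and in the value table from all measured probe sets. The percentile describes these arrays and is not a test. The GAP and GEF table is the study's own choice of genes, and how it was chosen is not given in the sources used here. Lists of Rab, Ras, Rap and Ral, and Arf GAPs, of RGS proteins and of cytokinesis genes were added after the table was seen.

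Genes were named by a rule fixed before the data were examined: the 12 highest and 12 lowest differences among genes measured in both groups whose other measured probe sets had the same sign, up to 4 members of each list of at least 2-fold, Arhgap24 and a set of marker and control genes whatever their value, and in the GAP and GEF table the 5 highest and 5 lowest differences and the 5 highest levels. The rule was written for the value table, and its first parts were applied to the GAP and GEF table too after both had been seen. Alternatives covered the scaling, the floor, the detection rule, the choice of probe set, the fold threshold and the source of the values.

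Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures drawn in matplotlib 3.10.9. The gene-level step for the GAP and GEF table was tested on simulated data with 4-fold changes in 30 of 140 genes: 30 were recovered and 0 others called. The step for the value table was tested with 200 changed probe sets of 27372, and 200 were recovered with 0 false calls. These simulations held technical noise alone. For the value table the changed probe sets were all bright and the changes far larger than the noise added, so full recovery was near certain. For the GAP and GEF table the changed genes were all present in both groups, all probe sets of a gene moved together and the noise was capped. Full recovery was thus likely there too.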

Results

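The study compared undifferentiated and differentiated cells of a conditionally immortalized mouse podocyte line. Podocytes are the epithelial cells whose foot processes cover the glomerular capillaries of the kidney. The comparison asks which regulators of small GTPases differ between dividing cells at 33 °C and growth-arrested cells at 37 °C. Each group had 1 array, so no difference below has a replicate check, and errors given as model SE are technical. In the GAP and GEF table, 284 of 374 probe sets were called present in undifferentiated cells and 293 in differentiated cells. The median model SE of a present signal was 10.1% in both groups. In the value table, the median signal over 45037 probe sets was 52.6 in undifferentiated and 77.3 in differentiated cells.

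In the GAP and GEF table, Arhgap24 had the largest difference among genes present in both groups. This GAP acts on Rac. Its signal was 140 in undifferentiated and 2541 in differentiated cells, 18.2-fold higher, a log2 difference of 4.18 ± 0.15 (model SE). A second Arhgap24 probe set read 132 in both groups, with a log2 difference of 0.0015 ± 0.12. Both of its signals lay above the 95th percentile of absent-called probe sets, which was 51.5 in undifferentiated and 68.3 in differentiated cells. Srgap3, a GAP of the Slit-Robo pathway, was 10.6-fold higher (log2 difference 3.40 ± 0.23), but its second present probe set had 0.11 and the mean over both was 1.76. Arap2, an Arf GAP, was 6.12-fold higher (2.61 ± 0.10). Tbc1d2b, a Rab GAP, was 6.08-fold higher, from 29.9 to 182 signal units (2.60 ± 0.61). The lower signal lay under that 95th percentile, and a floor at the 40th percentile of signals reduced the difference to 1.54. Arhgef19, a GEF, was low in both groups and had a log2 difference of 2.21 ± 1.13, within 2 model SE.

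Other genes were lower in differentiated cells. Racgap1, a subunit of centralspindlin in cytokinesis, was 2182 in undifferentiated and 509 in differentiated cells, with a log2 difference of -2.10 ± 0.28. Its other present probe set had the same direction. Depdc1a had a log2 difference of -2.31 ± 0.09 and Arhgap19 of -2.55 ± 0.39. Iqgap3 was 2.83-fold lower, at 1556 and 551 signal units. Depdc1b had the lowest difference, -2.67, with a model SE of 1.41 and a differentiated signal of 15.1; a floor at the 40th percentile reduced it to -0.62. Sipa1, a GAP of Rap proteins, had -1.80 ± 0.17, and Rangap1, the GAP of Ran in nuclear transport, had -1.51 ± 0.08. The Rab GAPs Tbc1d1 and Usp6nl had -1.36 ± 0.49 and -1.21 ± 0.27.

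Of 151 measured genes in the GAP and GEF table, 28 were at least 2-fold higher in differentiated cells, 10 were at least 2-fold lower, and 113 lay within 2-fold. Of the 38 genes past 2-fold, 34 differed by more than 2 model SE. These include Tbc1d8, Garnl3, Rgs1 and Rgs2, which were called absent in undifferentiated cells. Their SE rests partly on an undetected signal, so for them it is no check of a difference. Among the 22 of the 38 genes with other present probe sets, all of these had the same sign in 19. The balance of higher and lower genes depended on scaling. With the 2 groups' medians set equal, log2 differences moved by -0.66, and 12 genes were higher and 33 lower. With the 75th percentiles set equal, 19 were higher and 17 lower, and after quantile normalization 20 were higher and 16 lower. The median log2 difference of all measured genes was 0.17 as deposited, -0.49 with equal medians, -0.083 with equal 75th percentiles and -0.012 after quantile normalization. With equal medians, 5 named genes fell under 2-fold: Als2cl (0.86), Arhgap20 (0.95), Arhgap23 (0.84), Dlc1 (0.81) and Arhgdib (0.41). Arhgdib did so with equal 75th percentiles (0.81) and after quantile normalization (0.71) too.

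**Figure D1:**
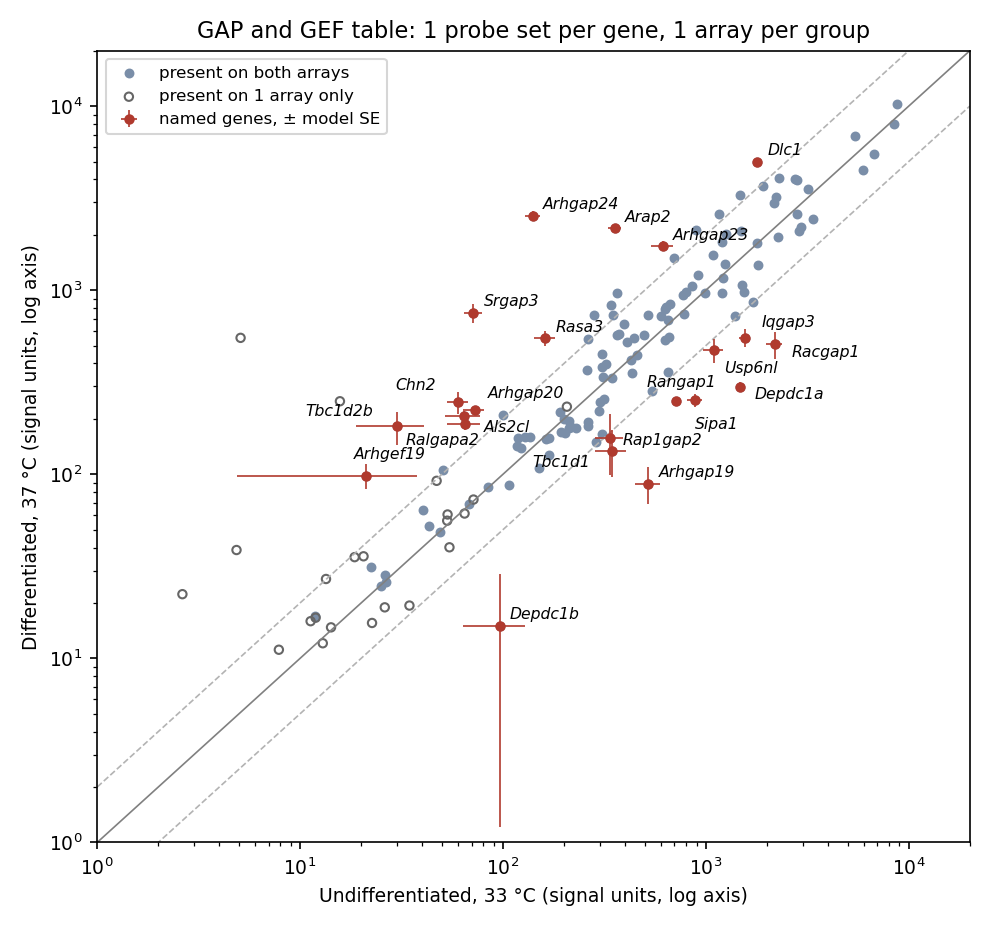
Signals of the GAP and GEF table in undifferentiated (x axis) and differentiated (y axis) podocytes, in signal units on log axes, for 1 probe set per measured gene. Open circles are genes called present in 1 group alone, red points are named genes with model SE, the solid line marks equality and dashed lines mark 2-fold; Arhgap24 lies 18.2-fold above equality and Racgap1 below it.

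Of the 28 higher genes, 5 were called absent in undifferentiated cells, so their folds are ratios to an undetected signal. Tbc1d8, a Rab GAP, was 551 in differentiated cells, 108-fold above its absent-called undifferentiated signal of 5.09. It was 10.7-fold above the 95th percentile of absent-called signals in undifferentiated cells. In the value table its differentiated signal was 77.7. Its log2 difference there, at least 0.77, is a bound, because its undifferentiated signal after normalization lay under the floor of 37.6. Garnl3 was 249 in differentiated cells, 15.9-fold above its absent-called undifferentiated signal but 4.84-fold above that percentile. Its value table signal in differentiated cells was 24.9 as deposited, and after normalization it lay under the floor of 37.6. Rgs1, Rgs2 and Rgs20 were at 22.3, 38.8 and 27.0, all under that percentile. These 5 genes were singled out after their values were seen.

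Among the other named genes, Chn2, a chimaerin, had a log2 difference of 2.03 ± 0.26, and Arhgap20 one of 1.62 ± 0.16. Arhgap23 was 2.83-fold higher, from 613 to 1737. Dlc1, a protein of focal adhesions, had 1.48 ± 0.05 and reached 5001 signal units in differentiated cells. Arhgdib was 99.9 in undifferentiated and 210 in differentiated cells (1.07 ± 0.44).

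Among GAPs of Ras, Rap and Ral, 6 of 15 measured members were at least 2-fold higher and 2 at least 2-fold lower. Rasa3, a Ras GAP, had a log2 difference of 1.77 ± 0.22, and Ralgapa2, a subunit of a Ral GAP complex, one of 1.68 ± 0.32. Sipa1 and Rap1gap2 (-1.10 ± 0.57) were the 2 lower members, and both act on Rap. The Sipa1 relatives Sipa1l2 (1.38 ± 0.33) and Sipa1l1 (0.28 ± 0.13) lay above 0, so GAPs of Rap had no common direction. The median of the list was 0.31 (80.2nd percentile), and -0.36 with equal medians. In the value table, 2 of 16 were higher and 5 lower past 2-fold, with a median of -0.24 (34.3rd percentile). Of 25 Rab GAPs, 4 were higher and 2 lower past 2-fold, with a median of 0.12 (35.6th percentile) that turned to -0.55 with equal medians. The value table had 4 of 24 higher and 3 lower, and a median of 0.20. Of 17 Arf GAPs, 1 was higher, Arap2, and 0 lower. Their median was 0.28 (48.8th percentile), and -0.39 with equal medians. Of 14 measured in the value table, 1 was higher and 3 lower, 10 lay below 0, and the median was -0.28 (28.5th percentile). Als2cl, related to a GEF of Rab5, had 1.52 ± 0.29.

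Further genes were named for the highest signals in differentiated cells, though signals of different probe sets do not rank expression between genes. Arhgap29, a GAP, was 8728 in undifferentiated and 10250 in differentiated cells (log2 difference 0.23 ± 0.13). Gdi2, which extracts Rab proteins from membranes, was 8455 and 8009 (-0.078 ± 0.087), and its 5 other present probe sets had the opposite sign. Arl2bp was 5462 and 6877 (0.33 ± 0.12). Equal medians turned Arhgap29 to -0.43 and Arl2bp to -0.33. Ranbp1, a partner of Ran, was 6712 and 5526 (-0.28 ± 0.10).

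**Figure D2:**
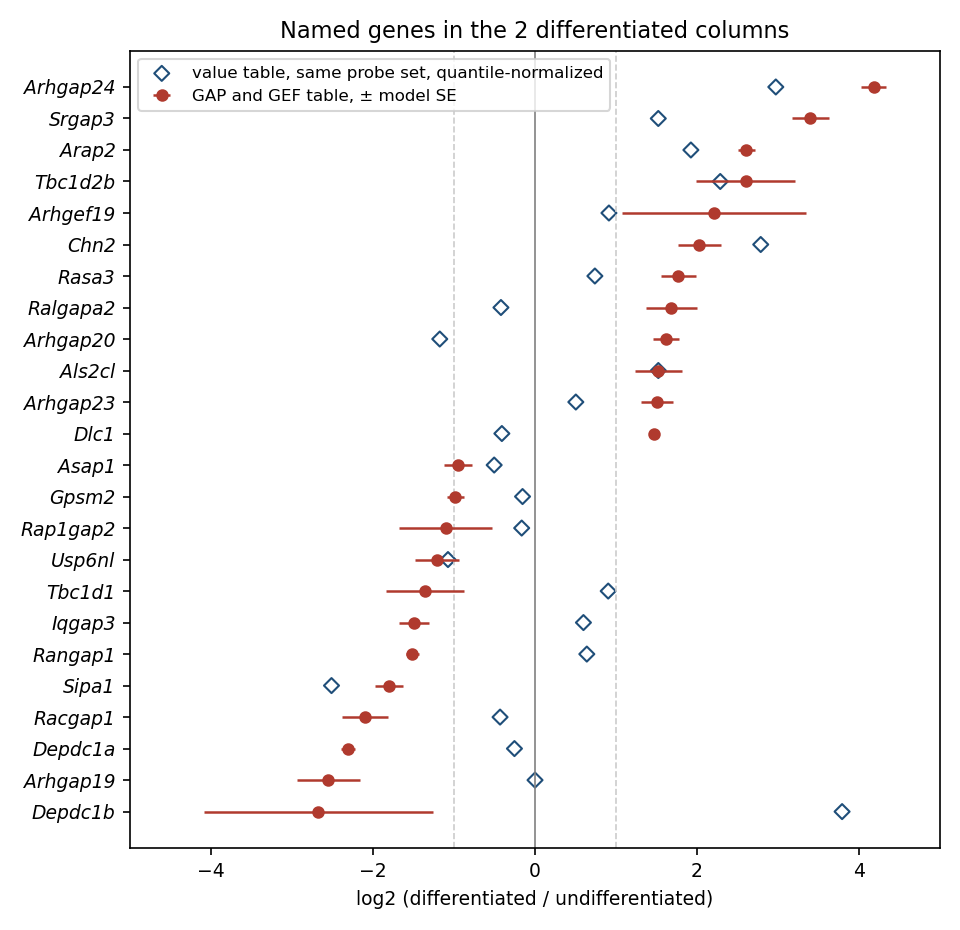
Log2 ratios of differentiated over undifferentiated signal for the 12 highest and 12 lowest named genes of the GAP and GEF table (red, with model SE), and for the same probe sets in the quantile-normalized value table (open diamonds). Dashed lines mark 2-fold. Arhgap24, Srgap3, Arap2, Tbc1d2b, Chn2 and Als2cl lie above 2-fold in both, and Sipa1 and Usp6nl below it in both. Depdc1b (-2.67 and 3.79) and Arhgap20 (1.62 and -1.18) lie past 2-fold on opposite sides.

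The same comparison in the value table used the other differentiated column. Arhgap24 was 7.86-fold higher there, from 140 to 1088 signal units (log2 difference 2.98), and its second measured probe set had the opposite sign. The mean of all Arhgap24 probe sets was 0.79, under 2-fold, and 2.09 in the GAP and GEF table. Among named genes, the highest difference between signals measured in both groups was that of Depdc1b, 3.79, against -2.67 in the GAP and GEF table. Arhgap42 (2.71), Arhgef15 (2.68), Rap1gap (2.62) and Arhgap12 (2.32) were also high, though the GAP and GEF table called Rap1gap and Arhgef15 absent in both groups. Tbc1d2b (2.29) and Arap2 (1.93) were past 2-fold in both sources, but the mean of all Arap2 probe sets was 0.42 in the value table. The lowest differences among named genes with signals measured in both groups were those of Syde1 (-4.67), Arhgap18 (-3.76), Rin1 (-2.93), Sh3bp1 (-2.61) and Sipa1 (-2.51). The same probe sets of the GAP and GEF table had -0.47 for Syde1, -0.85 for Arhgap18, 0.49 for Rin1, 0.64 for Sh3bp1 and -1.80 for Sipa1. Of the 12 highest and 12 lowest genes, 21 were present in both groups of the GAP and GEF table, and 16 of the 21 had the same sign there. The genes were chosen for extreme differences and both differences share the undifferentiated array, so the count is no measure of reproducibility.

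Further named genes of the value table rested on bounds. Arhgap27 was at least 14.6-fold higher, with an undifferentiated signal of 9.98 and a differentiated signal of 517. The mean of all Arhgap27 probe sets had a log2 difference of 1.83, and the same probe set had 2.13 in the GAP and GEF table. Another Arhgap27 probe set, which represented the gene in the GAP and GEF table, had the opposite sign in both sources. It had -0.21 in the value table and -0.84, a bound, in the GAP and GEF table. Tiam2, a GEF of Rac, was at least 7.66-fold lower, and Plekhg6 at least 3.46-fold lower. Arhgef1 had a log2 difference of -2.08 and Arhgdig one of -2.34, both between measured signals. The other measured probe set of Arhgef1 had the opposite sign, and the mean of its probe sets was -0.84, under 2-fold. In the GAP and GEF table Arhgef1 had -0.28 and Arhgdig -0.45.

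Across the whole value table, 6709 of 31831 measured probe sets were at least 2-fold higher in differentiated cells and 7018 at least 2-fold lower, together 43.1%. With equal medians in place of quantile normalization the split was 4957 higher and 10192 lower, and the median log2 difference moved by -0.35. As deposited it was 7390 and 6573, and with equal 75th percentiles 7815 and 6183. These counts are of 2 arrays that also differed in RNA kit and in signal distribution, and they have no error estimate.

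The 2 differentiated columns differed more from each other than the groups did within the GAP and GEF table. Over the 264 probe sets present in both groups of that table, Spearman's correlation across probe sets was 0.90 between undifferentiated and differentiated signals, and 0.70 between the 2 differentiated columns. Probe sets are not independent replicates. At least 2-fold differences between groups were found for 65 of the 264 probe sets (24.6%) in the GAP and GEF table and for 119 (45.1%) in the value table. Within 72 genes with several present probe sets, the SD of log2 differences among probe sets of a gene was 0.55 in the GAP and GEF table and 1.29 in the value table. For these shares and SDs, the GAP and GEF table's signals were as deposited and the value table's were quantile-normalized and floored. The probe sets were chosen by the GAP and GEF table's calls alone, so the 2 sources are not treated alike. Of the 28 genes at least 2-fold higher in the GAP and GEF table, 17 were above 0 in the value table, 10 at least 2-fold higher and 3 at least 2-fold lower. Garnl3 and Rgs1, among the 28, lay at the value table's floor in both groups. Of the 10 lower genes, 5 were below 0, 2 at least 2-fold lower and 1 at least 2-fold higher. Among 137 genes measured in both sources, 10 were at least 2-fold higher in both, against 3.80 for independent lists, and 2 were at least 2-fold lower in both, against 2.70. Both comparisons share the undifferentiated array. The log2 differences of the 129 genes present in both groups had a correlation of 0.28 and a covariance of 0.41, against 0.039 and 0.058 on average when only the shared array's model error was simulated. The upper limits of the simulated 95% intervals were 0.22 and 0.33, so both lay past them. Of the 129 genes, 52.7% had the same sign, against a simulated 51.0% with an upper limit of 59.7%. Genes at the value table's floor in both groups, such as Rgs8 and Stard8, had 0 there and counted as not the same sign. The simulation held no such values, so the 2 shares are not quite alike. Other errors of the shared array were not simulated.

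**Figure D3:**
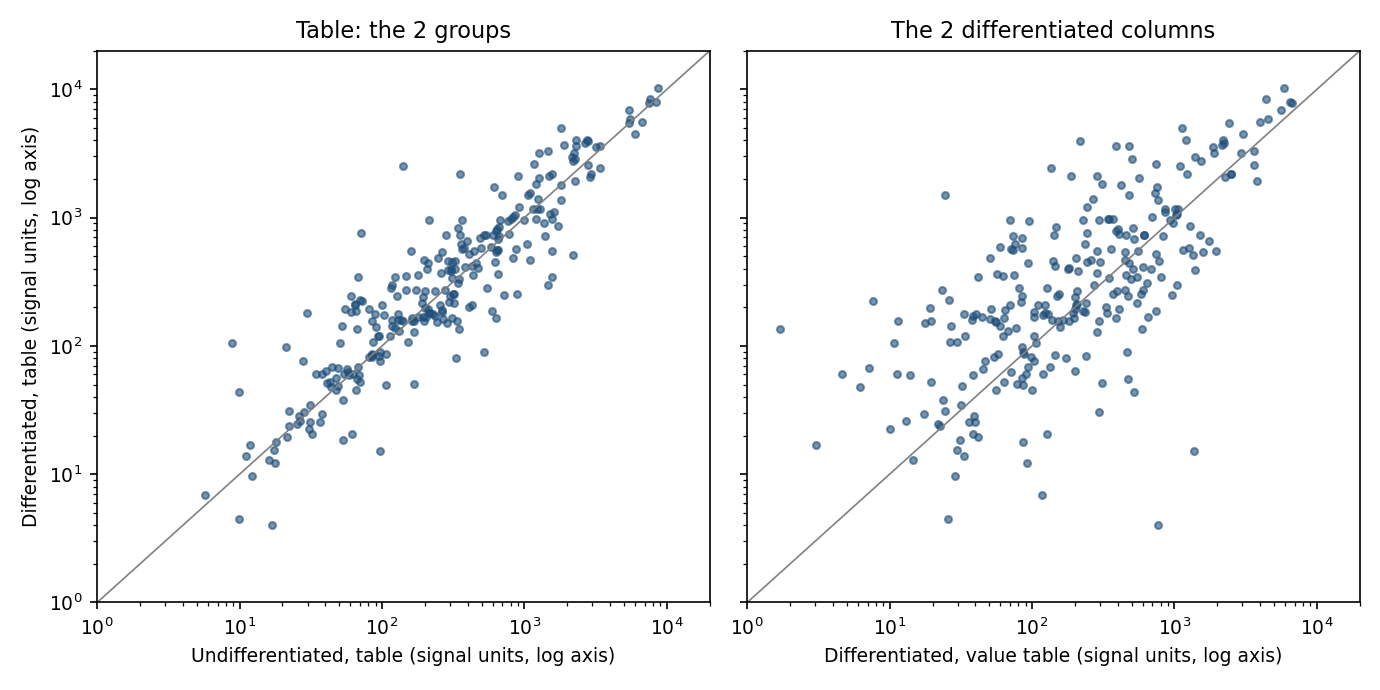
Signals of the 264 probe sets present in both groups of the GAP and GEF table, in signal units on log axes, with the line of equality. The table's differentiated signal (y axis) is plotted against its undifferentiated signal on the left, with a Spearman correlation of 0.90, and against the value table's differentiated signal on the right, with 0.70.

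Control probe sets of the value table gave the balance of 3′ and 5′ signal within a transcript. For Gapdh the 3′ signal was 12921 in undifferentiated and 7841 in differentiated cells, and the 5′ signal was 14892 and 2078. The ratio of 3′ to 5′ was thus 0.868 and 3.77. For beta-actin it was 1.09 and 1.54, for the transferrin receptor 1.94 and 1.82, and for pyruvate carboxylase 1.51 and 5.93, the last 2 with weak signals. Bacterial transcripts were spiked in as poly-A controls. The 6 controls with a 3′ signal of at least 100 on the differentiated array are pairs for lys, phe and thr. They had high ratios there, from 3.92 for PheX to 42.8 for LysX. The other 3, with weaker signals, had 1.67 (DapX), 1.95 (TrpnX) and 0.465 (the second dap control). Its hybridization controls, added after labelling, had ratios between 0.940 and 1.64.

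**Figure D4:**
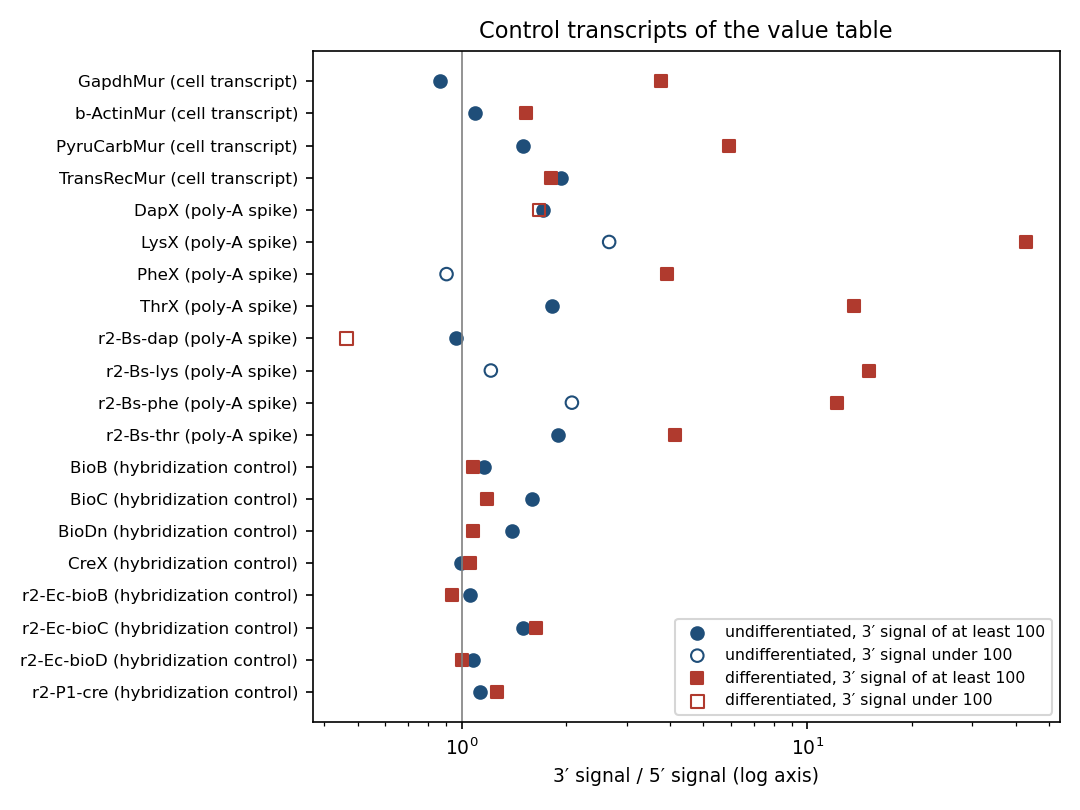
Ratio of 3′ to 5′ signal (log axis) for control transcripts of the value table on the undifferentiated (circles) and differentiated (squares) arrays; open symbols have a 3′ signal under 100. Hybridization controls lie near 1 on both arrays, while poly-A controls of the differentiated array range from 0.465 to 42.8.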

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

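For the GAP and GEF table, the 1.5-fold and 4-fold thresholds, the floor at the 40th percentile and the rule of present calls in both groups, and for the value table the other source for its genes, were chosen after seeing the data. In the value table, a floor at the 60th percentile gave 4268 higher and 4436 lower probe sets and a 4-fold threshold 2637 and 2674. The other scalings, floors and probe set filters stayed within 1.5 times of 6709 and 7018. In the GAP and GEF table, median centring gave 12 higher and 33 lower genes, against 28 and 10, with a median of -0.49. Setting the 75th percentiles equal gave 17 lower genes and a median of -0.083, and quantile normalization 16 lower genes and a median of -0.012. These shifts follow from the scaling itself. A floor at the 60th percentile left 16 higher genes. It raised low signals, as in Arhgap20 (0.10), Chn2 (0.25) and Arhgdib (0.019), and left 5 named genes unmeasured: Als2cl, Arhgef19, Depdc1b, Ralgapa2 and Tbc1d2b. A 4-fold threshold gave 10 higher and 4 lower genes, and a 1.5-fold threshold 18 lower. The value table's differentiated array gave 37 lower genes and a median of -0.16.

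Of the 29 genes named from the GAP and GEF table, the mean of all probe sets moved 14, among them Srgap3 (1.76) and Als2cl (0.86), and turned Gdi2 to 0.050. A pseudocount in place of the floor took Als2cl (0.97), Arhgef19 (0.94), Arhgdib (0.75) and Rap1gap2 (-0.86) under 2-fold. Floors, and shifts smaller than a gene's difference, cannot turn a sign, and most genes were named because their probe sets, where several, shared a sign, so these settings are no check of direction. The value table gave 9 of the 23 past 2-fold the opposite sign: Arhgap19 (0.0014), Arhgap20 (-1.18), Arhgdib (-0.040), Depdc1b (3.79), Dlc1 (-0.41), Iqgap3 (0.60), Ralgapa2 (-0.42), Rangap1 (0.64) and Tbc1d1 (0.91). These are the GAP and GEF table's probe sets; the one that the value table's rule chose for Dlc1 had 1.48. Of the 29 named from the value table, the mean of all probe sets moved 7, among them Arap2 (0.42), Arhgap12 (0.71) and Arhgap24 (0.79). Of the 26 present in both groups of the GAP and GEF table, 6 had the opposite sign there: Arhgap17 (0.17), Depdc1b (-2.67), Plekhg6 (0.27), Rin1 (0.49), Sh3bp1 (0.64) and Tsc2 (0.34). The cause of these reversals was not tested gene by gene. For the whole-array counts, the mean of all probe sets of a gene was not run, since names were not used there. No paired analysis was possible because each group had 1 array. Genes with a signal near those of absent-called probe sets, such as Depdc1b, Arhgef19 and Tbc1d2b, are limited by signal over background. A floor at the 40th percentile left -0.62, 0.65 and 1.54.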

Other observations

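All tests in this part were chosen after the values were seen, except that of rows out of register. In the GAP and GEF table, 7 genes known from cytokinesis or mitosis (Racgap1, Depdc1a, Depdc1b, Iqgap3, Arhgap11a, Arhgap19 and Gpsm2) were all lower in differentiated cells, 5 of them past 2-fold, though Depdc1b had -0.62 with a floor at the 40th percentile. Gpsm2, which helps orient the spindle, had a log2 difference of -0.98 ± 0.11, and Arhgap11a one of -0.23 ± 0.07. Their median was -2.10, at the 0.045th percentile of random lists, and between -2.76 and -2.10 under all scalings tried. The list was picked after its values were seen, so the percentile overstates how far it stands apart. A hypothesis is that the cells behind both differentiated columns, whether 1 culture or 2, held fewer dividing cells, as the labels' growth arrest would give. It predicts a fall in the value table too. There the median of the same 7 genes was 0.0014, with 95% of random lists between -1.14 and 1.04, and 4 of the 7 were above 0. This argues against a fall of these signals as large as -2.10 in both columns. A smaller fall, within the range of the random lists, cannot be told from none. Probe sets of a gene hardly share differences in the value table, so its 0.0014 may describe the array more than the cells, and whether division fell in them stays open.

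RGS proteins act on heterotrimeric G proteins. Of 11 measured in the GAP and GEF table, 3 were at least 2-fold higher and 0 lower. The 3 are Rgs1, Rgs2 and Rgs20, all bounds with signals under the 95th percentile of absent-called probe sets. The median log2 difference was 0.17 (78.1th percentile) and turned to -0.49 with equal medians. Of 11 measured in the value table, 3 were higher and 2 lower, with a median of 0.79 (95.3rd percentile). The 3 higher (Rgs16, Rgs2 and Rgs20) are bounds, and the GAP and GEF table called the probe sets used for Rgs16, Rgs2, Rgs17 and Rgs7 absent in both groups. Rgs5, a marker of mesangial cells and pericytes, was absent in undifferentiated cells on all of its probe sets, and its highest signal in differentiated cells was 25.3.

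The 2 differentiated columns differed although both are labelled differentiated. Rows out of register over part of the value table would give blocks with no correlation between the arrays. The lowest Spearman correlation over blocks of 1000 consecutive probe sets was 0.45 and the highest 0.84, so no whole block was unrelated, but the lowest fell short of the bound of 0.5 set for excluding it, and shorter stretches stay open. Probe sets bright in both groups of the GAP and GEF table differed too. Over 76 with table signals of at least 500 in both groups, the SD of log2 ratios between the 2 differentiated columns was 1.44. Between the table's groups it was 0.63 (95% bootstrap interval of the difference 0.53 to 1.09). The limit of 500 held for both signals of the second ratio but not for the value table's signal in the first. The 2 SDs are thus not alike, and signals dim on the value table's array stay open. Gene-level differences between separate cultures as the main part are argued against. They would be shared by the probe sets of a gene, and the intraclass correlation of these log2 ratios was 0.21 (0.029 to 0.37 over 72 genes), while that of the table's own differences between groups was 0.66 (0.48 to 0.81). For the value table's differences between groups it was 0.18 (-0.0015 to 0.33), so differences named from that table are little shared by the probe sets of a gene. A difference in labelling, RNA quality or signal model that acts probe set by probe set stays open, as does a smaller difference between cultures.

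The high 3′ to 5′ ratios of the value table's differentiated array were weighed against degraded cell RNA alone. Spiked poly-A transcripts are not cell RNA. The lowest log2 ratio among 6 spiked controls with a 3′ signal of at least 100, in pairs for lys, phe and thr, was 1.97. Their median was 3.69, against at most 0.71 for the hybridization controls. The limit of 100 is on the 3′ signal, the numerator of the ratio, so it favours high ratios. The controls it left out had log2 ratios of 0.74 (DapX), 0.97 (TrpnX) and -1.10 (the second dap control). For the 6 controls kept, degradation of cell RNA before the spikes were added is not enough if the spikes were intact and alike on both arrays. Their 3′ signals differed: DapX was 382 on the undifferentiated and 30.4 on the differentiated array, and LysX 70.5 and 4071. The spikes thus cannot decide the state of the cell RNA. Cell transcripts of the differentiated array had ratios from 1.54 (beta-actin) to 5.93 (pyruvate carboxylase), against 3.92 to 42.8 for the 6 controls. Short copies made in the labelling reaction, or loss after the spikes were added, may account for the ratios and could act unevenly on the probe sets of a gene. Probe positions were not used here, so that link was not tested, and no biological explanation of the ratios was tested.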
